A study of Homo sapiens with 12 samples.

How the data were processed

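The deposited table holds RNA-seq values of 12 libraries of DU145 cells. Per the labels, the libraries were made from total RNA with a stranded TruSeq kit, and the authors used Salmon (version not given in the sources used here) with genome build hg38; the annotation release is not given in the sources used here. The values deposited by the authors are expected counts (estimated counts of reads per gene from Salmon), already rounded to whole numbers and not scaled for depth. Each of the 21439 genes in the table has a count of at least 1 in all 12 libraries, so genes at 0 in any library are not in it, and genes switched fully on or off could not be analysed here. Totals ran from 17760878 to 19202632 counts per library. Reads carry no molecular identifiers that the sources mention, so precision was taken from the spread between replicates.

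Groups were taken from the sample titles: siCtrl, siATF6, DMSO and Ceapin, with 3 libraries each. The columns of the control siRNA carry the prefix NC and were matched to siCtrl replicates 1 to 3 by elimination and number. The labels conflict at one point: a field on transfection names the control siRNA for the DMSO libraries and the ATF6 siRNA for the Ceapin libraries, whereas titles and treatment text give these cells only DMSO or Ceapin-A7. The ATF6 mRNA level, given with the results, was read as the check on this. It bears on the ATF6 siRNA in the Ceapin libraries and cannot show whether the DMSO libraries received the control siRNA. All 12 libraries were used.

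Gene symbols came from a reference gene table (21201 genes with a symbol), and positions and 3′ UTRs from a GENCODE v29 annotation of GRCh38. In R 4.3.3, edgeR 4.0.16 was run on the counts of all 12 libraries with the filter filterByExpr by group (3616 genes removed, 17823 tested). It used TMM scaling and a quasi-likelihood fit with 1 term per group and 8 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The contrasts were siATF6 minus siCtrl, Ceapin minus DMSO, the difference between these 2 effects, and DMSO minus siCtrl as background for the closing section. Log2 fold changes are given with standard errors derived from the quasi-likelihood F statistic. CPM values are TMM-scaled, with the mean and SD of 3 replicates. Overlaps of called genes were tested with two-sided Fisher's exact tests against independence among the tested genes.

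Before the data were examined, 33 gene lists were fixed from general knowledge of ER stress, lipid synthesis, cell cycle, apoptosis, inflammation, stress responses, markers of other cells and RNA quality. They were tested with camera from limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the 33 lists within each contrast. For each list the members past the threshold were counted over all tested genes and again with p-values adjusted over the list alone. Camera with an estimated correlation and the rotation test fry were run beside it.

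The genes named in the text follow a rule also fixed before the data were examined: ATF6; per comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM and all 3 treated libraries on the same side of all 3 controls; up to 4 members per list by smallest p; up to 6 genes per direction shared by both comparisons and up to 3 per opposite pattern; and 5 per direction for the difference. Rows named only by a clone or locus were skipped. Among the largest changes, genes whose reads can be shared with copies elsewhere in the genome and most genes whose call ended without 1 library were left unnamed. A few genes named where the rule did not place them, chosen after their values were seen, complete small counts or illustrate the closing section. They are XBP1, CALR, HYOU1 and DNAJC3 in the chaperone list, DDIT3, VEGFA, PTGS2, and CDH1, CXCL8 and CDKN1A between the control groups. Of these, CALR, VEGFA, CDH1, CXCL8 and CDKN1A meet the rule for another list or comparison.

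The alternatives were DESeq2 size factors or library totals in place of TMM, no filter on low counts, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0 or limma-voom in place of edgeR, only the 6 libraries of a comparison, the replicate number as a block, thinning every library to the smallest total (17760878), each library left out in turn, a stricter adjusted p of 0.01, a minimum log2 fold change of 1, and for lists the other set tests. The pipeline was tested on simulated data: of 50 genes given a 1.5-fold change, 33 were called in the siRNA comparison and 35 in the Ceapin-A7 comparison, with 13 and 12 calls among 17623 unchanged genes.

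For the closing section, each of 16384 7-base sequences was tested for enrichment in the 3′ UTRs of called genes against 13433 tested genes with a 3′ UTR of at least 50 bases, within 10 bins of length by 5 of GC content, and compared with 100 random gene lists matched the same way. Each gene was represented by the 3′ UTR of a single transcript, so its other transcripts may carry a sequence where none is reported. In simulated lists 5 of 5 planted sequences were found first. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for this step, and matplotlib 3.10.9 for the figures.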

Results

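RNA of DU145, an androgen-independent human prostate cancer cell line, was sequenced in 12 libraries that form 4 groups of 3. In the siRNA arm, cells received an siRNA against ATF6 (siATF6) or a control siRNA (siCtrl) and were cultured for 24 h. In the compound arm, cells received 10 µM Ceapin-A7 (Ceapin) or its solvent (DMSO) for 12 h. ATF6 is a transcription factor anchored in the membrane of the endoplasmic reticulum (ER). Under ER stress it is cleaved, and the released part turns on genes of the unfolded protein response. Ceapin-A7 is a small molecule that holds the ATF6 protein in the ER. Thapsigargin, an inhibitor of the ER calcium pump that causes ER stress, was given at 30 nM for 3 h before harvest in all 4 groups, so no unstressed cells were sequenced.

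The total counts of replicates 1, 2 and 3 were 17782165, 19202632 and 17856418 in siCtrl and 18877582, 19008183 and 19028088 in siATF6. They were 18347774, 17760878 and 18226771 in DMSO and 19185124, 18364203 and 17977507 in Ceapin. Of 21439 genes in the table, 17823 passed the filter on low counts and were tested. The first principal component, with 62.4% of the variance, parted the siRNA arm from the compound arm. Transcripts of the mitochondrial genome took 6.94% ± 0.256 (SD, n = 3) of the counts in siCtrl and 7.36% ± 0.190 in siATF6. They took 9.92% ± 0.359 in DMSO and 10.2% ± 0.222 in Ceapin.

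ATF6 itself (ENSG00000118217; GRCh38 chromosome 1, 161766294 to 161964070, + strand, a protein-coding gene) stood at 124.6 ± 1.08 CPM (the counts-per-million scale; mean ± SD, n = 3) in siCtrl and at 25.8 ± 0.810 in siATF6. Its mRNA was 4.84-fold lower after the siRNA (log2 fold change −2.27, SE 0.0379, edgeR adjusted p = 9.4e-30), the smallest value in siCtrl lying above the largest in siATF6. In the compound arm ATF6 stood at 71.4 ± 1.99 CPM in DMSO and 72.9 ± 1.91 CPM in Ceapin, a difference smaller than the spread between replicates (log2 fold change 0.03, SE 0.0344, edgeR adjusted p = 0.748).

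**Figure D1:**
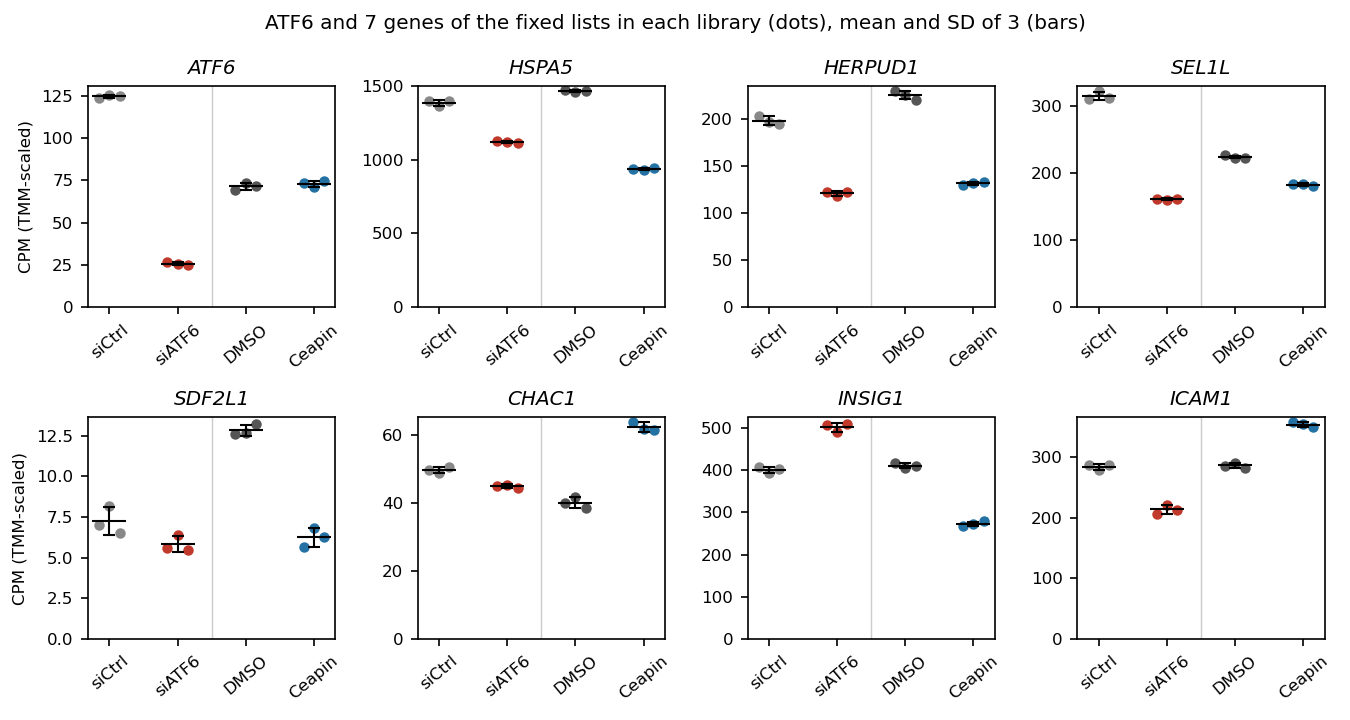
CPM (y axis of each panel) of ATF6, HSPA5, HERPUD1, SEL1L, SDF2L1, CHAC1, INSIG1 and ICAM1 in each of the 12 libraries, by group, with points for libraries and bars for the mean and SD of 3. ATF6 is lowest in siATF6 (25.8 CPM, against 124.6 in siCtrl, 71.4 in DMSO and 72.9 in Ceapin), HERPUD1 is lower in both treated groups than in their controls, and INSIG1 is higher in siATF6 (502.8 against 400.7 CPM) and lower in Ceapin (273.4 against 411.2 CPM).

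siATF6 against siCtrl asks what the RNA of stressed cells looks like when ATF6 mRNA is depleted. After ATF6 siRNA 12 of 15 genes of the ER chaperone list, 11 of 26 interferon-stimulated genes and 9 of 18 NF-kB target genes fell. SEL1L (chromosome 14, 81471549 to 81533861), the adaptor of the ubiquitin ligase that removes misfolded ER proteins, fell from 314.9 ± 6.12 to 160.9 ± 1.46 CPM (log2 fold change −0.97, SE 0.0235). SPCS3, a subunit of the signal peptidase, fell from 89.9 ± 2.94 to 45.0 ± 1.31 CPM. HERPUD1, another ER degradation factor (chromosome 16, 56932048 to 56944863), fell from 198.0 ± 4.64 to 120.9 ± 2.83 CPM (−0.71, SE 0.0271). HSPA5, the main ER chaperone BiP (chromosome 9, 125234853 to 125241330), fell from 1386 ± 19.4 to 1122 ± 7.84 CPM (−0.30, SE 0.0183).

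Of 15 tested members of the list ATF6-dependent ER chaperones, 12 fell, 1 (CALR) rose and 2 did not pass after ATF6 siRNA. Adjusted over the list alone, 13 fell and 1 rose. The median log2 fold change was −0.24 (camera adjusted p = 9.2e-10, and 0.0048 with an estimated correlation). SDF2L1 was counted among the 12 with −0.32 (SE 0.109, adjusted p = 0.0231), a call lost without siCtrl replicate 2 (adjusted p = 0.189), siATF6 replicate 1 (0.0818) or siATF6 replicate 3 (0.0946), and also lost with DESeq2 (0.0714) and with thinned counts (0.0698). Of 21 genes of ER-associated degradation, 9 fell and 2 rose (10 and 3 adjusted over the list alone; adjusted p = 3.7e-04), with DERL1 at −0.73. The call was lost at adjusted p = 0.0605 with an estimated correlation. SEL1L, HERPUD1 and SYVN1 stand in both lists, so the chaperone list does not hold chaperones alone.

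Of 26 interferon-stimulated genes, 11 fell and 15 did not pass after ATF6 siRNA (12 fell adjusted over the list alone; median −0.19, adjusted p = 4.1e-04, and 0.0244 with an estimated correlation). OAS3, a sensor of double-stranded RNA, changed by −1.19 and HERC6 by −0.80. Of 18 NF-kB and inflammatory cytokine genes, 9 fell and 9 did not pass (11 fell adjusted over the list alone; median −0.13, adjusted p = 3.7e-04, and 0.0244 with an estimated correlation), among them ICAM1 at −0.41, BIRC3 at −0.46 and LIF at −0.47. Of 22 pro-apoptotic genes, 9 fell, TNFRSF10B (a TRAIL receptor, −0.33) and BMF (−0.61) among them, and 2 rose (9 and 2 adjusted over the list alone; adjusted p = 0.0129, lost at adjusted p = 0.0947 with an estimated correlation).

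Of 30 members of the list G2/M and mitosis, 17 rose and 3 fell after ATF6 siRNA (17 and 3 adjusted over the list alone; median 0.12, adjusted p = 4.1e-04, lost at adjusted p = 0.0889 with an estimated correlation), with BIRC5 at 0.38 and TPX2 at 0.34, while AURKA, a mitotic kinase, fell (−0.68). Of 26 genes of G1/S and DNA replication, 12 rose and 3 fell (13 and 3 adjusted over the list alone; adjusted p = 0.0063, lost at adjusted p = 0.0605 with an estimated correlation), with RRM2 at 0.58 and MCM2 at −0.46. Of 21 homologous recombination genes, 9 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.0075, lost at adjusted p = 0.0605 with an estimated correlation). Of 16 cytosolic heat-shock genes, 7 rose and 1 (HSPB1, −0.61) fell (8 and 1 adjusted over the list alone; adjusted p = 6.1e-04, lost at adjusted p = 0.162 with an estimated correlation). Of 21 NRF2 targets 9 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.0125, lost at adjusted p = 0.0651 with an estimated correlation), with ME1 at 0.71. Of 13 mitochondrially encoded genes 12 rose (12 adjusted over the list alone; adjusted p = 1.8e-04). Of 32 cytosolic ribosomal protein genes 17 rose and 4 fell (17 and 4 adjusted over the list alone; adjusted p = 0.0063). Both calls were lost at adjusted p = 0.331 with an estimated correlation.

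The other 21 lists did not pass after ATF6 siRNA (camera adjusted p from 0.0814 to 0.999). Members went both ways among PERK/ATF4/CHOP targets (12 rose and 8 fell of 31; TRIB3 0.52, PSAT1 −0.46), ER folding and disulfide enzymes (6 and 8 of 19) and IRE1/XBP1s targets (3 and 6 of 20). They also did among sensors of the unfolded protein response (2 and 3 of 12), cholesterol genes (10 and 4 of 23) and fatty acid genes (3 and 5 of 15). The same held for anti-apoptotic genes (2 and 5 of 10), p53 targets (4 and 6 of 19), immediate-early genes (6 and 5 of 17), and ferroptosis genes (5 and 7 of 21). It held as well for autophagy and lysosome genes (9 and 7 of 27), peroxisome genes (3 and 4 of 24), aryl hydrocarbon receptor genes (3 and 1 of 11), epithelial-mesenchymal genes (5 and 7 of 19) and androgen-dependent prostate genes (2 and 2 of 7). Of hypoxia genes 3 rose and 9 fell of 22, a list that passed without siCtrl replicate 2 (adjusted p = 0.0403). Of 9 replication-dependent histone genes 4 rose, a list that passed without siCtrl replicate 1 (adjusted p = 0.0358) or siATF6 replicate 1 (0.0493). Median and mean differed in sign, or from the direction of the test, in the lists of ER folding, PERK/ATF4/CHOP, peroxisome, androgen-dependent and endothelial genes. Of the markers of other cells, 1 of 3 neuroendocrine genes fell. Of the 18 tested leukocyte, fibroblast and endothelial markers, 0 passed by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05.

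Over all genes, 2869 rose and 2720 fell after ATF6 siRNA (edgeR, Benjamini-Hochberg adjusted p under 0.05), 31.4% of those tested. The median change of the called genes was 1.18-fold, and 138 (31 up, 107 down) changed at least 2-fold. After ATF6 itself the largest falls were those of ADPRH (−2.15, SE 0.132), F13A1 (−1.94, SE 0.0736), the kinase gene MELK (130.6 ± 3.48 to 34.2 ± 1.49 CPM, −1.93, SE 0.0372), ENPP5 (−1.66) and SAMD5 (−1.61). Among the largest rises were the NRF2 target SRXN1 (1.32, SE 0.166), GANAB, the catalytic subunit of ER glucosidase II (1.24, SE 0.0233), TPM4 (1.13), PRDX4 (1.10) and NOLC1 (1.08). GANAB, TPM4 and NOLC1 were each lower in siCtrl than in the other 3 groups. The 3′ untranslated regions (UTRs) of genes that fell were enriched for the 7-base sequence GAGTCAT, found in 482 of 2505 against 284.5 expected, and in 92 of 2669 that rose against 176.1 expected. ATF6, ENPP5, SAMD5, SPCS3, DERL1, AURKA, MCM2, PHLDA1, PSAT1, DNAJB9, BIRC3 and LIF carry it, as does ERO1A, which rose (0.24). ADPRH, F13A1 and MELK do not carry it. HSPA5, HERPUD1, SEL1L and the other 12 chaperone-list members do not, but SEL1L, HERPUD1, HYOU1, DNAJC3 and SYVN1 carry GAGTCA or AGTCAT, its 6-base parts. F13A1, OAS3, HERC6, TNFRSF10B and BMF also carry GAGTCA or AGTCAT, whereas ADPRH and MELK carry neither. Of the 10 chaperone-list members with neither part, 8 fell. Among members with neither part in other lists, 1 of 7 genes of ER-associated degradation fell. The same count was 5 of 16 for interferon-stimulated genes and 5 of 12 for pro-apoptotic genes.

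Ceapin against DMSO asks what changes when the ATF6 protein is targeted and its mRNA is not. After Ceapin-A7 14 of 15 genes of the ER chaperone list and 17 of 23 cholesterol genes fell, and 21 of 31 PERK/ATF4/CHOP targets and 13 of 18 NF-kB target genes rose. HSPA5 fell from 1466 ± 6.90 to 938.6 ± 6.15 CPM (log2 fold change −0.64, SE 0.0184, edgeR adjusted p = 1.5e-22) and HERPUD1 from 225.0 ± 4.29 to 131.4 ± 1.92 CPM (−0.78, SE 0.0265). SDF2L1, a component of ER chaperone complexes (chromosome 22, 21642261 to 21644298), fell from 12.8 ± 0.352 to 6.24 ± 0.584 CPM (−1.04, SE 0.0990). CXCL8, which encodes the chemokine interleukin 8, rose from 197.1 ± 6.49 to 376.0 ± 2.64 CPM (0.93, SE 0.0260, adjusted p = 1.3e-22).

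Of 15 tested members of the list ATF6-dependent ER chaperones, 14 fell after Ceapin-A7 and 1, XBP1, did not pass (0.07). Adjusted over the list alone, 14 fell and XBP1 rose. The median was −0.34 (camera adjusted p = 7.0e-55, and 7.1e-06 with an estimated correlation). Of 19 ER folding enzymes 10 fell (13 adjusted over the list alone; adjusted p = 6.5e-13), with PDIA4 at −0.26 and CALR at −0.19. PDIA4, PDIA6 and CALR also stand in the chaperone list, so the list of folding enzymes overlaps with it and is not wholly separate evidence. Of 21 ER-associated degradation genes 6 fell (6 adjusted over the list alone; adjusted p = 1.2e-09), with SEL1L at −0.30 and SYVN1 at −0.24. Of 20 IRE1/XBP1s targets 1, DNAJB9 (−0.23), fell (3 adjusted over the list alone; adjusted p = 0.0068, lost at adjusted p = 0.0545 with an estimated correlation).

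Of 31 PERK/ATF4/CHOP targets, 21 rose, 2 fell and 8 did not pass after Ceapin-A7 (25 rose and 2 fell adjusted over the list alone; median 0.18, adjusted p = 2.8e-36, and 4.5e-04 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, rose by 0.64 (SE 0.0399), SESN2 by 0.44, DDIT4 by 0.47 and SLC3A2 by 0.34. The 2 that fell, looked up after the values were seen, were DDIT3 (−0.35), which encodes CHOP itself, and the growth factor gene VEGFA (−0.09). Of 12 sensors of the unfolded protein response, 2 rose and 1 fell (adjusted p = 0.135; 0.0393 without Ceapin replicate 2), with ERN1, the gene of the sensor IRE1, at 0.48.

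Of 23 genes of cholesterol synthesis and uptake, 17 fell and 6 did not pass after Ceapin-A7 (19 fell adjusted over the list alone; median −0.16, adjusted p = 3.4e-39, and 2.5e-05 with an estimated correlation). INSIG1, which retains the sterol sensor SCAP in the ER, fell from 411.2 ± 5.19 to 273.4 ± 5.01 CPM (−0.59, SE 0.0233). IDI1 changed by −0.39, STARD4 by −0.37 and HMGCS1 by −0.29. Of 15 fatty acid synthesis genes 6 fell (9 adjusted over the list alone; adjusted p = 6.4e-11), with SCD at −0.22 and FASN at −0.18. Of 26 genes of G1/S and DNA replication 7 fell (10 adjusted over the list alone; adjusted p = 2.0e-06), with CDC6 at −0.17. Of 22 hypoxia and glycolysis genes 6 fell (7 fell and 1 rose adjusted over the list alone; adjusted p = 3.2e-04), with LDHA at −0.13. These calls held with an estimated correlation.

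Of 18 NF-kB and inflammatory cytokine genes, 13 rose and 5 did not pass after Ceapin-A7 (17 rose adjusted over the list alone; median 0.30, adjusted p = 1.4e-35, and 1.3e-05 with an estimated correlation), with CCL20 at 0.99 and ICAM1 at 0.31. Of 10 anti-apoptotic genes 4 rose (7 adjusted over the list alone; adjusted p = 2.1e-10, and 7.0e-04 with an estimated correlation), with BIRC3 at 0.33 and MCL1 at 0.19. BIRC3 stands in the NF-kB list too, so these lists are not wholly separate evidence. Of 17 immediate-early genes 6 rose and 2 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0085, and 0.0431 with an estimated correlation), with EGR1 at 1.05 and MYC at 0.39 but FOSB at −0.48. Of 16 cytosolic heat-shock genes 3 fell (4 adjusted over the list alone; adjusted p = 2.1e-06), with HSPA8 at −0.40. Of 11 aryl hydrocarbon receptor genes 2 fell and 1 rose (2 and 1 adjusted over the list alone; adjusted p = 0.0122), with CYP1B1 at −0.94. With an estimated correlation both were lost, at adjusted p = 0.0516 and 0.0516.

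The mitochondrially encoded genes were shifted up and the cytosolic ribosomal protein genes down as lists after Ceapin-A7 (camera adjusted p = 0.0068 for each), and both were lost with an estimated correlation, at adjusted p = 0.492 and 0.352. The first was also lost without DMSO replicate 2 (adjusted p = 0.210), DMSO replicate 3 (0.212) or Ceapin replicate 3 (0.344), and the second without DMSO replicate 2 (0.0567) or Ceapin replicate 2 (0.0958). With the sensors of the unfolded protein response, 17 lists had adjusted p from 0.135 to 0.959. Few members passed among pro-apoptotic genes (3 rose and 1 fell of 22; PMAIP1 0.40), NRF2 targets (2 and 4 of 21), ferroptosis genes (4 and 2 of 21) and androgen-dependent genes (1 and 1 of 7). The same was true of epithelial-mesenchymal genes (2 fell of 19), p53 targets (1 rose of 19), interferon-stimulated genes (1 fell of 26), autophagy and lysosome genes (1 rose of 27) and histone genes (1 fell of 9). In the p53, NRF2, ferroptosis and epithelial-mesenchymal lists the median, the mean and the direction of the test differed in sign. Of the 141 members of the lists of peroxisome, mitosis, homologous recombination, mitochondrially encoded, ribosomal protein, neuroendocrine, leukocyte, fibroblast and endothelial genes, 0 passed by edgeR, 0 by DESeq2 and 1 by limma-voom, and 19 had an unadjusted p under 0.05.

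Over all genes, 394 rose and 429 fell after Ceapin-A7 (edgeR, Benjamini-Hochberg adjusted p under 0.05), 4.62% of those tested. The median change of the called genes was 1.14-fold, and 20 genes (9 up, 11 down) changed at least 2-fold. With 3 replicates at this depth, simulated changes of 1.2-fold were called for 19 of 50 genes and simulated changes of 2-fold for 37 of 50, so a gene that did not pass may still have changed, even 2-fold. The simulation drew its changed genes from all levels of expression and changed fewer than passed here. These shares are therefore only a guide and not the power of this comparison. Replicates within a group differed by more than counting error (chi-square per degree of freedom 1.41 to 1.88 over the 12 pairs, common coefficient of variation 1.95%), and the sources used here do not say whether they were separate cultures. The SEs and p-values measure the spread among these libraries, which need not be that between separate cultures.

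**Figure D2:**
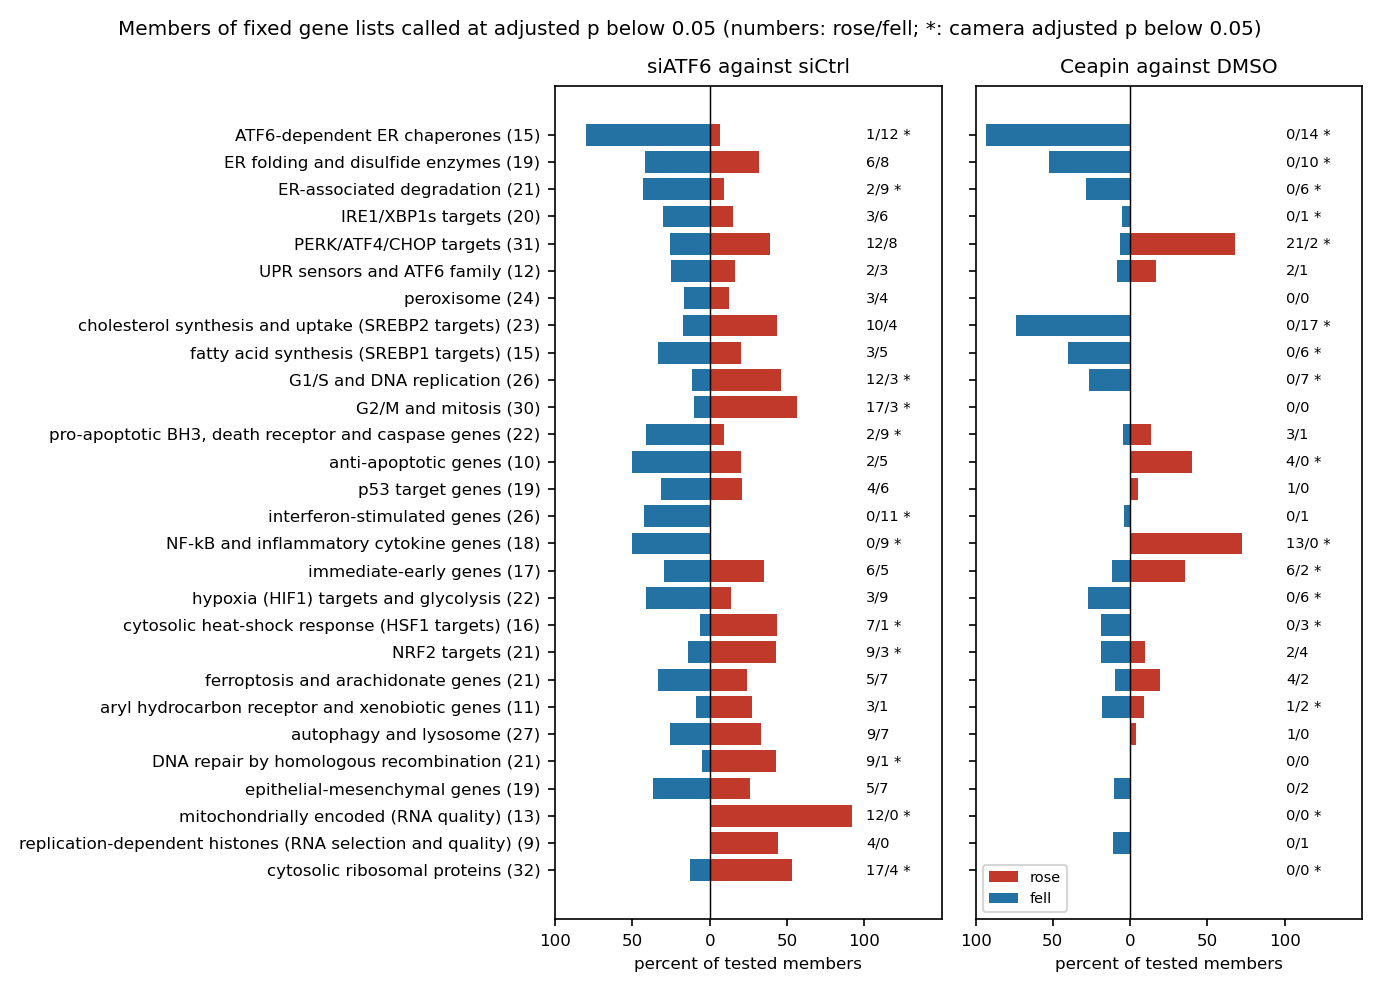
Share of tested members (x axis, percent) that rose (to the right) or fell (to the left) in 28 fixed gene lists after ATF6 siRNA (left panel) and after Ceapin-A7 (right panel), with counts rose/fell beside the bars, list sizes in brackets and asterisks for camera adjusted p below 0.05. Members of the chaperone list fell in both panels (12 and 14 of 15), whereas of 18 NF-kB genes 9 fell after the siRNA and 13 rose after the compound.

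The study set both ways of inhibiting ATF6 side by side. Of the 15 members of the chaperone list, 12 fell in both. HERPUD1 fell by a like amount in both (difference 0.06, SE 0.0381, edgeR adjusted p = 0.252), whereas HSPA5 fell further after Ceapin-A7 (difference 0.34, SE 0.0259, adjusted p = 3.6e-12) and SEL1L further after the siRNA (difference −0.67, SE 0.0337, adjusted p = 9.7e-17). The 3′ UTRs of SEL1L and HERPUD1 carry GAGTCA or AGTCAT, and that of HSPA5 carries neither. CRELD2 (−0.37 and −0.58) and BMF (−0.61 and −0.81) also fell in both, and CEBPB (0.42 and 0.49), MYC (0.35 and 0.39) and DKK1 (0.31 and 0.31) rose in both. PHLDA1 went opposite ways (−0.53 after the siRNA, 0.53 after the compound), as did NPTX1 (0.51 and −0.53), CYP1B1 (0.50 and −0.94) and INSIG1 (0.33 and −0.59).

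As lists, the NF-kB genes (camera adjusted p of the difference 2.9e-17, and 3.9e-04 with an estimated correlation), the cholesterol genes (1.1e-11, and 0.0031) and the G1/S genes (1.6e-05, and 0.0127) differed between the 2 effects. The chaperone list (0.0036) and the PERK/ATF4/CHOP list (1.3e-06) also differed by camera, but both calls were lost at adjusted p = 0.0546 with an estimated correlation. Of 488 genes called in both comparisons, 258 changed the same way and 230 opposite ways. Falls were shared by 144 genes against 65.5 expected by independence (odds ratio 2.91, 95% interval 2.35 to 3.58; two-sided Fisher's exact p = 1.3e-21) and rises by 114 against 63.4 (odds ratio 2.17, Fisher's exact p = 9.8e-11). Opposite pairs also exceeded independence: 115 genes fell after the siRNA and rose after the compound (60.1 expected, Fisher's exact p = 1.5e-12). The reverse held for 115 genes (69.1 expected, Fisher's exact p = 1.1e-08). Of the genes shared the same way 174, and of those that went opposite ways 154, lay in the highest of 5 expression groups of 3564 or 3565 genes. Independence over all tested genes leaves out this shared power to detect changes. Across the tested genes the 2 sets of log2 fold changes were uncorrelated (Pearson r = −0.0078, Spearman −0.0020; genes are not independent replicates). Each comparison has its own control group; arm, culture time and delivery differ together between them.

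**Figure D3:**
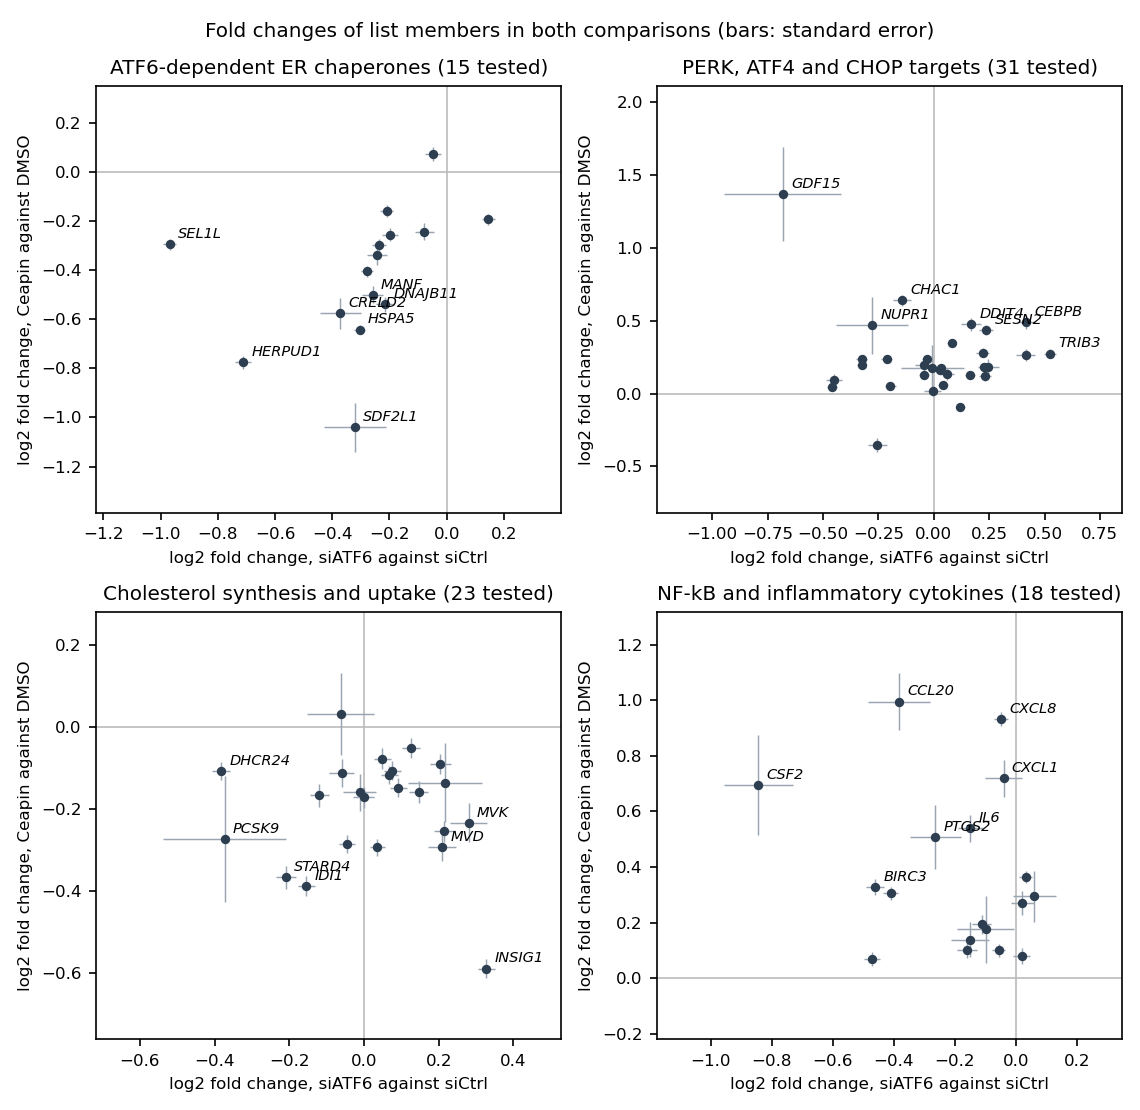
Log2 fold change after ATF6 siRNA (x axis) against log2 fold change after Ceapin-A7 (y axis) of the tested members of 4 lists, 1 panel each, with bars for the SE. Members of the chaperone list lie mostly below 0 on both axes (medians −0.24 and −0.34), cholesterol genes below 0 on the y axis only (medians 0.05 and −0.16), and NF-kB genes left of 0 and above it (medians −0.13 and 0.30).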

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

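The tests of carriers of the enriched 7-base sequence among all genes, the tests with its 6-base parts and the counts over other splits of the libraries were chosen after the result was seen; the tests for seed matches, depth and NF-kB members with the whole sequence were planned before.

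The effects of ATF6 siRNA and Ceapin-A7 differed for 4167 genes by the test of the difference (edgeR, 2194 higher and 1973 lower after the siRNA). Among the genes that went opposite ways, the log2 difference was −1.06 for PHLDA1, 1.04 for NPTX1 and 1.44 for CYP1B1. It was −1.54 for CSF2, −1.03 for L3MBTL3 and 0.91 for TGFB3, whose Ceapin-A7 or siRNA calls rest on single libraries. CSF2 had adjusted p = 0.0520 to 0.124 for Ceapin-A7 without DMSO replicate 1 or 2 or Ceapin replicate 1 or 2. L3MBTL3 had 0.0507 to 0.199 without any 1 of siCtrl replicates 1 to 3, DMSO replicates 1 to 3 or Ceapin replicates 1 to 3. TGFB3 had 0.0610 for the siRNA without siCtrl replicate 2 and 0.0611 for Ceapin-A7 without Ceapin replicate 2. The genes with the smallest p for a higher effect of the siRNA were TPM4 (1.27), GANAB (1.27), NOLC1 (1.06) and INSIG1 (0.92), with CYP1B1. Those with the smallest p for a lower effect were ATF6 (−2.30), ADGRG6 (−1.36), MELK (−1.91) and PYGB (−1.51), with PHLDA1.

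Of the 33 lists, 16 differed between the 2 effects by camera, and NF-kB (adjusted p = 2.9e-17), cholesterol (1.1e-11), G1/S (1.6e-05) and interferon-stimulated genes (8.3e-04) also with an estimated correlation. Those that did not hold with an estimated correlation were cytosolic heat-shock genes (9.5e-07), PERK/ATF4/CHOP targets (1.3e-06), mitosis genes (8.3e-04), ribosomal protein genes (8.3e-04), ER chaperones (0.0036), anti-apoptotic genes (0.0036), fatty acid genes (0.0126), pro-apoptotic genes (0.0149), NRF2 targets (0.0172) and homologous recombination genes (0.0206), with adjusted p from 0.0546 to 0.223 with an estimated correlation. The mitochondrially encoded list (0.0071) was also lost with an estimated correlation (adjusted p = 0.478) and without siCtrl replicate 1 (0.0852) or DMSO replicate 1 (0.0630), and ER folding enzymes (0.0246) with an estimated correlation (adjusted p = 0.0912) and without siCtrl replicate 2 (0.0518).

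The ATF6 siRNA changed 6.79 times as many genes as Ceapin-A7. Depth is excluded as the cause, since with every library thinned to the smallest total the ratio was 6.89. Matches to the seed of the ATF6 siRNA may account for part of the excess: GAGTCAT was enriched in the 3′ UTRs of genes that fell (z = 13.1, against at most 4.29 in 100 matched random lists), not among genes that fell after Ceapin-A7 (z = −0.02), but the siRNA sequence is not given in the sources used here, so the match could not be read. Among 12412 searched genes without GAGTCAT the ratio was still 6.59 (4600 against 698 calls). Among 8058 without GAGTCA or AGTCAT, 1 of which is in each of the 5 most enriched sequences, it was 6.71 (2739 against 408). Both ratios count rises too, which a seed match would not give directly, so they had to stay high and do not decide about falls. Of genes without GAGTCAT, 20.8% rose after the siRNA and 2.66% after Ceapin-A7, and 16.3% and 2.96% fell. Direct matches to the whole sequence therefore do not make up the excess of falls. Whether genes changed in turn through carriers was not tested. What stays open and untested is a biological difference between losing ATF6 mRNA for 24 h and holding back the protein for 12 h, as well as other effects of transfection with this siRNA. An effect of the control siRNA on siCtrl, left undecided below, stays open too.

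The NF-kB list was lower after ATF6 siRNA and higher after Ceapin-A7. Seed matches could lower it after the siRNA, and 3 of its 18 members (LIF, BIRC3 and PTGS2) carry GAGTCAT. The 15 members without it were still lower (limma camera, adjusted p = 0.0039 over the 2 comparisons, median −0.10) and were higher after Ceapin-A7 (adjusted p = 2.9e-32, median 0.29). So were the 9 members with neither GAGTCA nor AGTCAT (limma camera, adjusted p = 0.0013, median −0.11, and 7.4e-19, median 0.29). This argues against 3′ UTR matches of members to these sequences as the whole cause. The test used the preset correlation only, and 4 of the 9 passed singly after the siRNA. Whether the opposite directions reflect the way of inhibition, the culture time or the arms' different control levels (CXCL8 at 668.2 CPM in siCtrl and 197.1 in DMSO) was not tested.

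For the siRNA comparison, 1 of the 10 splits of its 6 libraries into 3 and 3, the real one, called as many as 5589 genes, and the highest other split called 0. For Ceapin-A7, 1 of 10 called as many as 823, and the highest other called 1. Splits of 6 libraries are too few for a share under 0.05. For the difference, 2 of 100 splits drawn gave 4167 genes or more, the real one included, and so did 2 of the 40 drawn first, before the number was raised to 100. The highest other, with 4200, keeps all 4 groups whole and swaps the names DMSO and Ceapin, so it points to the structure of the samples and not to chance; 9 splits that kept only the siRNA groups whole gave 2973 to 3192, and those that kept only the compound groups whole at most 26. The number of splits as large therefore follows the siRNA effect, and it does not decide whether chance can be excluded for the difference.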

How the results depend on the processing

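The alternatives were all chosen before the data were examined, and none reversed a direction that had passed its test. The counts of genes changed by ATF6 siRNA, by Ceapin-A7 and in their difference stayed within 1.5 times of 5589, 823 and 4167 under every scaling, filter, tool and left-out library, with exceptions only at stricter thresholds. At adjusted p under 0.01, 472 genes were called for Ceapin-A7 and 143 changed the same way in both. With a log2 fold change of at least 1, 138 genes were called for the siRNA, 20 for Ceapin-A7, 198 for the difference and 0 for the same way in both (against 258 by edgeR with no minimum change). These follow from the thresholds themselves. The lists called after ATF6 siRNA were 3 with an estimated correlation and 24 with fry, against 12, and in the difference 4 with an estimated correlation, against 16; fry does not compare a list with other genes. The difference has no value with only the 6 libraries of 1 comparison.

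Leaving out 1 library gave 4861 to 5599 genes for the siRNA, 578 to 846 for Ceapin-A7, 3763 to 4055 for the difference and 185 to 253 for the same way in both. The correlation of the effects across genes stayed between −0.0157 and 0.0035, ATF6 between −2.29 and −2.26 after the siRNA and between 0.01 and 0.05 after Ceapin-A7, and the chaperone list between adjusted p = 4.6e-11 and 2.4e-09, and 5.7e-57 and 1.2e-53. DESeq2 called 4482 and 608 genes, of which 4473 and 591 were among the edgeR calls. With library totals in place of TMM, 2637 genes rose and 2888 fell after the siRNA (2869 and 2720 with TMM), 448 and 358 after Ceapin-A7 (394 and 429), and 1888 were higher and 2196 lower in the difference (2194 and 1973), so which direction holds more genes depends on the scaling. Over the single genes, 5085 values kept their side of the threshold, 119 lost it and 6 gained it; over the lists the numbers were 1256, 37 and 36. The replicate block gave 5538 and 783 genes and shared 5488 and 767 with edgeR without it. Of the genes followed by name, 3 lost their Ceapin-A7 call (BMP2, L3MBTL3 and SQSTM1). Libraries of equal number did not resemble each other (correlations −0.01 to 0.03), so no pairing by number was visible. Whether libraries of equal number were handled together cannot be told from this. Depth limits small changes of genes with few counts.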

Other observations

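The tests of other splits and of the seed of the control siRNA were chosen after the result was seen, and the contrast of the control groups was planned as background.

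The 2 control groups, both under thapsigargin, differed far more than either treated group did from its own control. DMSO differed from siCtrl in 11026 genes (5557 higher and 5469 lower, 61.9% of those tested), and 1579 differed at least 2-fold. Among the largest rises in DMSO were SFTPB, a surfactant protein gene (log2 4.28), the endothelin gene EDN2 (4.09) and MAP2K6 (3.88), and among the largest falls OLAH (−4.58), the proton pump subunit gene ATP6V0D2 (−4.14) and SPINK1, a trypsin inhibitor gene (−4.08). CDH1, the gene of E-cadherin, stood at 15.8 ± 0.367 CPM in siCtrl and 152.0 ± 2.76 in DMSO (mean ± SD, n = 3; log2 3.27), CXCL8 was lower in DMSO (−1.76), as was CDKN1A, the gene of the cell cycle inhibitor p21 (−1.59), and ATF6 itself was lower in DMSO (−0.80). By titles and treatment text, transfection, culture time and solvent differ together between these groups, so none of them can be singled out. The field on transfection conflicts with this for DMSO, and the ATF6 level cannot settle it. Of the 10 splits of these 6 libraries, 1 called as many genes and the highest other called 0, which is too few splits for a share under 0.05.

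A hypothesis on the siRNA comparison concerns its control. The 3′ UTRs of genes that rose after ATF6 siRNA were enriched for TGGAGAA (597 of 2669 genes against 482.0 expected, z = 6.40, at most 4.72 in 100 matched random lists). Of searched genes that rose at least 2-fold, 2 carry it and 16 do not (11.1% against 10.5% expected), so these few large rises showed no enrichment. A candidate explanation is that the control siRNA lowers genes that match its seed, so that these appear to rise in siATF6. Provided that the DMSO libraries received no control siRNA, it would make the same sequence enriched among genes higher in DMSO than in siCtrl. The z there was 2.38, between the bounds set for yes (3) and no (1), so the explanation stays undecided. Both contrasts share the siCtrl libraries. Levels of GANAB were 318.4 CPM in siCtrl against 752.7, 716.4 and 701.9 in siATF6, DMSO and Ceapin, those of TPM4 256.9 against 563.1, 576.7 and 524.4, and those of NOLC1 199.6 against 421.6, 369.0 and 373.1. Of these 3 genes GANAB carries TGGAGAA in its 3′ UTR, and TPM4 and NOLC1 do not.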
